A study of Mus musculus with 8 samples.

How the data were processed

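Messenger RNA was measured in c-Kit-positive bone marrow cells, a fraction rich in haematopoietic stem and progenitor cells, taken from individual mice, which are the replicates, 4 weeks after injection of PIpC, the inducer of the Mx1-cre recombinase. Per the labels' protocols, c-Kit (Cd117) cells were enriched on antibody-coated magnetic beads, RNA was isolated with Trizol, and libraries were made with a directional kit. There were 8 libraries in 4 groups of 2: controls that carried a floxed Smc3 allele without Mx1-cre, Smc3 del/+, Flt3-ITD, and Flt3-ITD with the Smc3 deletion, called the combined group here. Only the controls lack Mx1-cre, so each comparison with control also compares presence of the recombinase. The labels name the combined group in more than one way: the genotype field has fl/del for Smc3, and the sample title has het.

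The authors deposited FPKM values (fragments scaled by transcript length and by the number of mapped fragments) in 2 tables of 23385 rows and the same 8 libraries. The submitters' processing notes name the mm9 mouse genome build, Cufflinks 2.0.0 and TopHat, without saying which step each served; the annotation and the use of strand are not given in the sources used here. Both tables hold 92 rows for ERCC spike-in RNAs and 23293 for mouse genes. In the deposited FPKM of the second table, values were rescaled in a way that depends on their level and brings the spike-in totals close to each other (13573 to 14697, against 9509 to 18628 in the first); how the authors did so is not given in the sources used here. The first table was used for the main results and the second as an alternative. No coordinates were used, because the reference at hand is of another build.

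FPKM tables hold no read counts, so depth was judged from low values, which lie on steps worth 1 read. The most frequent ratio of values under 0.3 FPKM between each library and control replicate 1, within a tolerance of 0.02 on the log2 scale, was taken as the ratio of the steps, leaving out values at 0.01. Relative to control replicate 1, this gave depths of 0.956 for control replicate 2, 0.843 and 1.02 for Smc3 del/+, 0.820 and 0.801 for Flt3-ITD, and 0.908 for combined replicate 1. For combined replicate 2 it gave 0.710, near the end of the fixed range of ratios searched, so that a much lower depth could not have been returned. That library also had 11076 genes listed at 0 and 171 between 0.01 and 0.1 FPKM, against 9107 and 849 in control replicate 1. Its depth may thus be lower than 0.710. The ratio was shared by 42 to 88 of 637 to 1078 low genes in the first 6 and by 12 of 216 in combined replicate 2, small shares that leave all these estimates uncertain. The depth in reads is unknown.

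Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend in the empirical Bayes step. Genes with a mean of at least 1 FPKM over the 8 libraries were tested (10854), without spike-ins, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Comparisons of single groups and the interaction came from 1 fit with 4 group means (4 residual degrees of freedom), in which all groups share the spread. Averaged effects of the Smc3 deletion and of Flt3-ITD came from an additive model of both (5 residual degrees of freedom). With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so the calls rest on the model across genes. Lists of genes fixed beforehand (24, of which 23 had at least 4 tested members) were tested with camera from limma, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Spike-in shares were compared with a two-sided exact permutation test.

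The genes named in the text follow a rule set before the data were examined, as were the designs, the lists and the alternatives given below. For the 3 main comparisons, these are the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries do not overlap. Where fewer than 5 passed in a direction, the genes with the smallest p, no overlap and a log2 fold change of at least 1 in size fill the places up to 5, given as values that did not pass. The other comparisons use 5 and 3 in place of 10 and 5. Each list described in detail gives up to 4 members with the smallest p, and Smc3, Flt3 and Kit are always given. Genes listed at 0 in every library of a group are given per library and without a fold, except for the interaction, where fitted values are printed.

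In values simulated with the spread of these data, 200 of 10854 genes were changed, drawn from genes of about 10 FPKM or more. The fit for Smc3 del/+ against control recovered 72.0% of changes of 1 and 98.0% of changes of 2 on the log2 scale. For Flt3-ITD against control these shares were 77.0% and 100%, and for the combined group against Flt3-ITD 70.0% and 99.0%. The fit of the interaction recovered 20.0% and 96.0%. Lower genes, which vary more between replicates, were not among the changed ones. Each simulated gene had the same spread in all groups, whereas the combined pair here varied more. These shares may therefore not hold for all tested genes. The alternatives were the second table, a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio and quantile scaling, no variance trend, the replicate number as a block, only the compared groups in the fit, and each library left out in turn.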

Results

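Gene expression was measured by RNA sequencing in c-Kit-positive bone marrow cells of individual mice, the replicates, in 8 libraries, 2 in each of 4 groups: controls without Mx1-cre, Smc3 del/+, Flt3-ITD, and Flt3-ITD with the Smc3 deletion (the combined group). Smc3 encodes a core subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromosome loops. Flt3-ITD is an internal tandem duplication that activates the Flt3 receptor kinase and is frequent in acute myeloid leukaemia. The series asks how the dose of cohesin acts in normal and in malignant blood formation. Mouse genes at 1 FPKM or more numbered from 10490 to 10843 per library. Relative read depth was put at 0.710 to 1.02 of control replicate 1 by an uncertain estimate that could not return much lower values. Replicates correlated at r = 0.975 in controls, 0.981 in Smc3 del/+, 0.976 in Flt3-ITD and 0.932 in the combined group, across 10854 genes that are not independent. No gene above 0.01 FPKM had the same value in both replicates of a group. The spike-in share of all FPKM was 1.83% ± 0.136 in controls, 2.50% ± 0.159 in Smc3 del/+, 2.42% ± 0.198 in Flt3-ITD and 2.76% ± 0.0921 in the combined group (SD, n = 2 each). Over both Flt3 backgrounds it was 2.63% ± 0.188 in libraries labelled with the Smc3 deletion against 2.12% ± 0.370 in the others (SD, n = 4; two-sided exact permutation test p = 0.0571, adjusted p = 0.114 over 2 comparisons). For Flt3-ITD carriers against the others, it was 2.59% ± 0.236 against 2.16% ± 0.406 (n = 4, exact permutation test p = 0.171, adjusted p = 0.171). The short RNA gene Mir5133 made up 12.9% and 6.20% of mouse FPKM in controls, 3.90% in Smc3 del/+ replicate 2 and 0 in the others. It is part of the total and so lowers the spike-in share of those libraries.

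**Figure D1:**
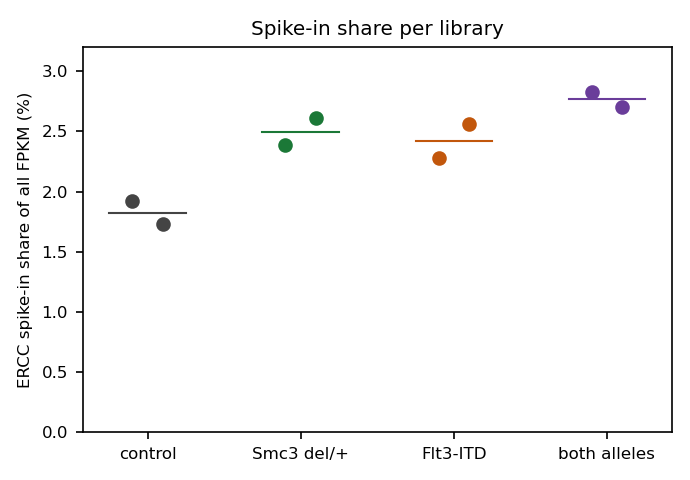
ERCC spike-in RNA as a percentage of all FPKM (y axis, linear from 0) for each library of the 4 groups (x axis); points are libraries and lines are means of 2. Controls lie at 1.92% and 1.73%, below the other 6 libraries, which lie between 2.28% and 2.83%. The total includes Mir5133, which made up 12.9% and 6.20% of mouse FPKM in controls and lowers their share.

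The targeted gene was examined first. Smc3 was at 115 ± 4.64 FPKM in controls, 134 ± 1.86 in libraries labelled Smc3 del/+, 92.3 ± 3.35 in Flt3-ITD and 119 ± 23.3 in the combined group (SD, n = 2 each). Libraries labelled with the Smc3 deletion thus had no lower Smc3 FPKM than their comparison groups: the log2 fold change was 0.21 ± 0.152 (SE) for Smc3 del/+ against control and 0.36 ± 0.152 for the combined group against Flt3-ITD, with limma adjusted p of 1 and 0.453. Without combined replicate 1 the second was 0.55 (adjusted p = 0.00901). In the table the authors normalized, the first of these values was -0.13, where the median of all genes was -0.38. FPKM of the whole gene does not tell transcripts of a deleted allele apart, and the labels do not say which part was removed. Every direction below therefore refers to libraries as labelled. Kit, used for the selection, was at 57.5 ± 3.74 FPKM in controls, 49.2 ± 0.469 in Smc3 del/+, 52.9 ± 6.71 in Flt3-ITD and 38.7 ± 1.86 in the combined group. Flt3 was at 5.51 ± 0.423, 4.84 ± 0.145, 4.50 ± 1.22 and 11.1 ± 4.52 FPKM in the same order, with no adjusted p under 0.05 in any comparison of this table with all 8 libraries. Without combined replicate 2, Flt3 passed in the combined group against Flt3-ITD (adjusted p = 0.0302) and against control (0.00728). In the normalized table, where the median of all genes was -0.577 in Flt3-ITD against control, Smc3, Flt3 and Kit had values of -0.83, -0.85 and -0.64 there (adjusted p = 0.00502, 0.0441 and 0.0232).

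Xist, the RNA that coats the inactive X chromosome in female cells, was at 637 ± 28.0 FPKM in controls and 548 ± 68.3 in the combined group, but at 0.680 ± 0.361 in Smc3 del/+ and 0.233 ± 0.132 in Flt3-ITD. Controls and the combined group therefore had a female pattern, and Smc3 del/+ and Flt3-ITD a male one. Each comparison of Smc3 del/+ or Flt3-ITD with control, and of the combined group with Flt3-ITD, is also a comparison between the sexes, and each comparison with control also sets Mx1-cre carriers against mice without it. The interaction follows sex in full. The averaged effects are balanced for sex, and the combined group shares the Xist pattern of the controls. Kdm6a, which escapes X inactivation and was chosen after its values were seen, was at 29.6 and 26.7 FPKM in controls, 17.6 and 19.4 in Smc3 del/+, 16.3 and 16.2 in Flt3-ITD, and 32.3 and 22.5 in the combined group.

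**Figure D2:**
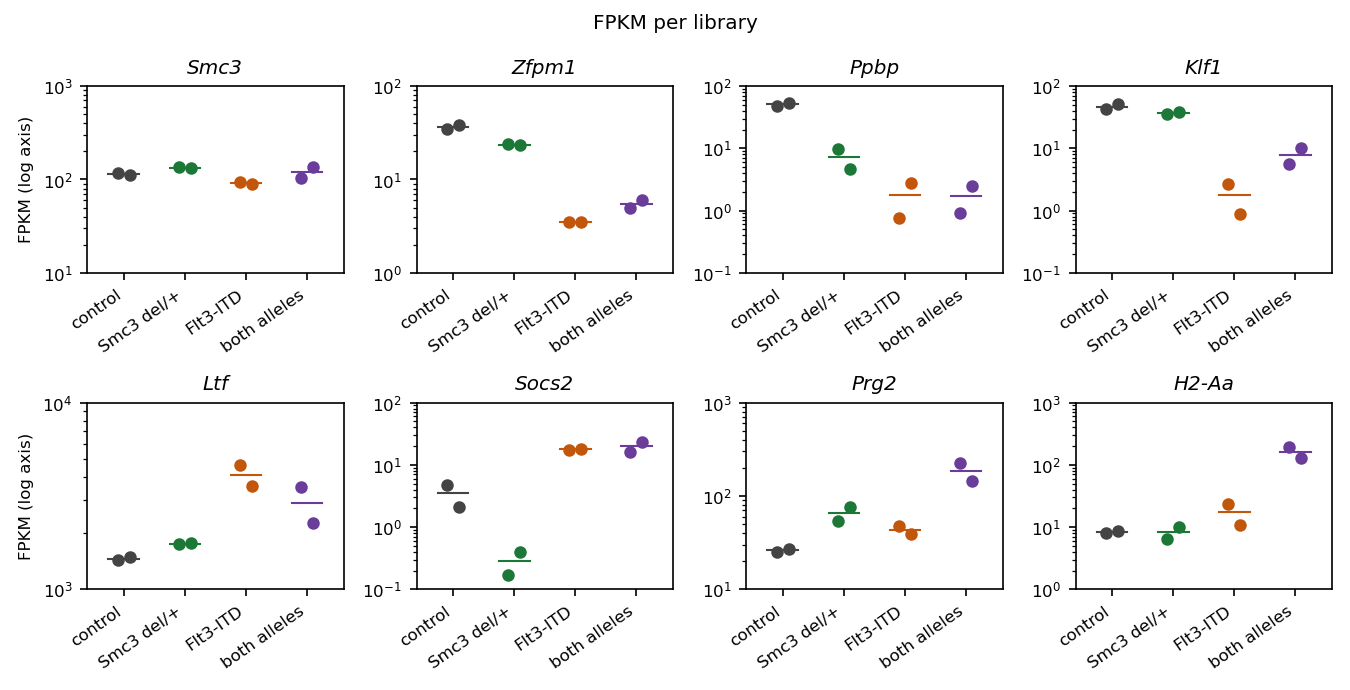
FPKM of 8 genes (y axes, logarithmic) in each library of the 4 groups (x axes); points are libraries and lines are means of 2. Smc3 was at 89.9 FPKM or more in every library, Zfpm1 and Klf1 were lowest in the groups with Flt3-ITD, and H2-Aa was at 131 FPKM or more in the combined libraries against 23.9 or less in the others.

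Megakaryocyte and platelet genes were lower as a group in libraries labelled Smc3 del/+ than in controls, in the comparison that asks what loss of 1 Smc3 allele does without the Flt3 mutation. All 18 tested members had lower means. Their median log2 fold change was -0.94 (camera adjusted p = 1.57e-22, and adjusted p = 0.00916 with an estimated correlation). Tubb1, the platelet beta-tubulin, was at 0.441 ± 0.0746 FPKM against 6.43 ± 0.891 in controls, and Ppbp, the platelet basic protein, at 7.12 ± 3.53 against 50.8 ± 3.43. Gp1ba, a subunit of the von Willebrand factor receptor, was at 6.11 ± 0.447 against 18.2 ± 2.37, and Clec1b, a platelet receptor, at 2.74 ± 0.118 against 7.72 ± 0.0663 (SD, n = 2). None of the 18 passed among all genes, while 10 were lower adjusted over the list alone. Their log2 fold changes were -2.36 ± 0.275 (SE) for Tubb1, -2.74 ± 0.46 for Ppbp, -1.43 ± 0.244 for Gp1ba and -1.22 ± 0.185 for Clec1b.

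Mast cell, basophil and eosinophil genes had a positive median of 0.61 in the same comparison, with 12 of 13 members higher (camera adjusted p = 5.26e-08, and adjusted p = 0.0611 with an estimated correlation). Prg2, the eosinophil major basic protein, was at 65.1 ± 14.8 FPKM against 26.3 ± 1.44. Cpa3, mast cell carboxypeptidase, was at 57.1 ± 0.745 against 32.3 ± 0.0241. Primary granule and granulocyte-monocyte progenitor genes had a median of 0.25 (adjusted p = 1.20e-06, and 0.0602 as the adjusted p with an estimated correlation). Fcnb was at 518 ± 7.50 against 290 ± 10.4 and Clec12a at 244 ± 17.8 against 176 ± 11.7 FPKM. B cell genes had a median of -1.13 (adjusted p = 2.06e-10, and adjusted p = 0.234 with an estimated correlation). Igll1, part of the surrogate light chain, was at 9.98 ± 1.67 FPKM against 50.9 ± 36.3, where the controls were at 76.6 and 25.2. Cd79a, a signalling subunit of the B cell receptor, was at 6.97 ± 1.10 against 20.7 ± 11.3. Type I interferon response genes had a median of -0.48 (adjusted p = 7.75e-08, and adjusted p = 0.234 with an estimated correlation). Isg15 was at 0.338 ± 0.238 against 2.74 ± 0.0075 FPKM. Adjusted over the list alone, 1 mast cell, basophil and eosinophil gene and 4 primary granule genes were higher, and 9 B cell genes and 1 interferon gene were lower. None of these passed among all genes.

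Hardly any single gene passed the threshold between Smc3 del/+ and control. Of 10854 genes, limma called 1, Xist, which follows the sex of the mice. An unadjusted p under 0.05 was seen in 494, where 542.7 would be expected by chance if the shared spread held for these groups. That spread includes the combined pair, whose replicates differed most. Their difference had an SD across genes of 0.701 on the log2 scale, against 0.393 in controls and 0.35 in Smc3 del/+. The p-values here can therefore be too large, and 494 does not show that the groups are alike. The libraries of these groups did not overlap in 5138 genes (47.3%), against 33.3% by chance, in genes that are not independent. The genes of smallest p that did not pass were, on the higher side, Chit1, a chitinase, at 10.2 ± 1.40 FPKM against 2.22 ± 0.0186 (log2 fold change 1.79 ± 0.174 SE, adjusted p = 0.0556), and Zfp534 at 28.0 and 43.2 against 4.56 and 1.83. Chi3l4 and Orm1 had log2 fold changes of 1.03 and 1.16. Chi3l4 has a near-identical paralog, which makes its value uncertain. Lower values that did not pass were Alox12, platelet 12-lipoxygenase, at 0.472 ± 0.174 against 5.82 ± 0.317, and Ceacam10 at 1.90 ± 0.247 against 10.2 ± 0.818. Rnu12, a small nuclear RNA, was listed at 0 in both controls and at 16.8 and 33.7 in Smc3 del/+. A further 9 lists passed camera with the preset correlation and not with an estimated one, among them lymphoid priming genes (median -0.24, adjusted p = 0.388 with an estimated correlation), G2 and mitosis genes (0.17, adjusted p = 0.478), ribosomal protein genes (-0.17, adjusted p = 0.513) and the cohesin list (0.15, adjusted p = 0.356). With the preset correlation, the cohesin list had an adjusted p of 0.0993 without control replicate 2 and 0.257 in the normalized table, and the ribosomal protein list of 0.0856 and 0.0896 without control replicate 1 and Smc3 del/+ replicate 1. With only the 2 compared groups in the fit, 22 genes were called. Leaving out 1 library gave 5 and 3 without control replicates 1 and 2, 3 and 3 without Smc3 del/+ replicates 1 and 2, 2 without Flt3-ITD replicate 2, and 12 and 12 without combined replicates 1 and 2. In the table the authors normalized, 2 were higher and 10 lower.

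Erythroid genes were far lower in Flt3-ITD than in control cells, in the comparison that asks what the Flt3 mutation does with both Smc3 alleles present. Values of the whole selected fraction do not tell a changed share of cells from changed expression within them, here and for the other lists of this comparison. Of 26 tested erythroid genes, 24 fell and none rose, also when adjusted over the list alone (median log2 fold change -3.46, camera adjusted p = 1.17e-18, and adjusted p = 0.263 with an estimated correlation). Zfpm1, a cofactor of GATA1, fell from 36.5 ± 2.81 to 3.50 ± 0.0474 FPKM (log2 fold change -3.06 ± 0.157 SE, limma adjusted p = 0.000153). The membrane skeleton genes Ank1, Sptb and Epb4.2 fell by 3.64, 2.98 and 3.40 on the log2 scale. Among the largest falls of all genes were Ermap (-4.89 ± 0.455), the water channel gene Aqp1 (-4.62 ± 0.478), Rhag (-4.40 ± 0.453) and the carbonic anhydrase gene Car1 (-4.33 ± 0.696).

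Megakaryocyte and platelet genes and B cell genes also fell in Flt3-ITD. In the first list 13 of 18 fell and none rose, 13 also adjusted over the list alone (median -1.84, camera adjusted p = 9.49e-08, and adjusted p = 0.0809 with an estimated correlation). Ppbp fell by 4.32, Gp1ba by 2.68, Tubb1 by 2.50 and the platelet integrin gene Itga2b by 1.62 on the log2 scale. Of 16 B cell genes, 12 fell, 14 adjusted over the list alone (median -2.97, adjusted p = 4.47e-09, and adjusted p = 0.263 with an estimated correlation). Igll1 had a log2 fold change of -5.44 ± 0.451 (SE), Cd79a of -4.01 ± 0.358, Blnk of -3.39 ± 0.376 and Pou2af1 of -3.21 ± 0.378. S phase genes fell by less: 9 of 22 passed, 12 adjusted over the list alone, all lower (median -0.49, adjusted p = 3.84e-06, and adjusted p = 0.602 with an estimated correlation). Ccne1, cyclin E1, went from 41.2 ± 3.39 to 11.5 ± 0.481 FPKM, and the replication genes Mcm2, Cdc6 and Chaf1b fell by 0.78, 0.90 and 0.79 on the log2 scale. The G2 and mitosis list had a median of 0.05 with no member called (camera adjusted p = 0.771). Of 29 ribosomal protein genes, 7 fell and none rose, 8 adjusted over the list alone (median -0.47, adjusted p = 1.44e-06, and adjusted p = 0.616 with an estimated correlation), Rps2 from 227 ± 3.62 to 113 ± 13.7 FPKM and Rplp0 from 594 ± 11.6 to 389 ± 28.1.

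Granulocyte and monocyte genes were higher in Flt3-ITD. Primary granule and granulocyte-monocyte progenitor genes rose in 7 of 16 cases, 9 adjusted over the list alone, with none lower (median 0.67, camera adjusted p = 8.41e-06, and adjusted p = 0.0814 with an estimated correlation). Clec12a, Igsf6, Hp (haptoglobin) and Fcgr3 had log2 fold changes of 0.94, 0.99, 0.98 and 0.86. In the normalized table these were 0.44, 0.51, 0.48 and 0.35 and did not pass, and neither did Cd177, Bcl6, Socs1, Klf6 and Ier2, named below, with 0.82, 0.74, 0.33, 0.53 and 0.32. In the secondary granule and mature neutrophil list, 7 of 18 rose and 1 fell, 12 and 1 adjusted over the list alone (median 1.24, adjusted p = 8.41e-05, and adjusted p = 0.313 with an estimated correlation). Ltf, lactoferrin, rose from 1462 ± 42.1 to 4113 ± 751 FPKM, and Itgam, Cd177 and Chi3l3 rose by 1.31, 1.31 and 1.25 on the log2 scale. The value of Chi3l3 is uncertain because of its paralog Chi3l4. The neutrophil transcripts S100a8, S100a9 and Ngp, put together after their values were seen and none past the threshold here (adjusted p = 0.118, 0.138 and 0.0795), together made up 27.1% ± 4.24 of mouse FPKM in Flt3-ITD, 12.9% ± 0.314 in controls, 17.5% ± 1.11 in Smc3 del/+ and 22.5% ± 0.604 in the combined group (SD, n = 2). Mir5133 is part of this total and lowers the shares in controls and in Smc3 del/+ replicate 2. Monocyte, macrophage and dendritic cell genes moved both ways, with 7 of 22 higher and 4 lower, 10 and 4 adjusted over the list alone (median 0.78, adjusted p = 0.0061, and adjusted p = 0.616 with an estimated correlation). Cybb, an NADPH oxidase subunit, and Ly86 rose by 1.36 and 1.13, while Axl and C1qb, which macrophages express, had log2 fold changes of -1.92 and -2.56. STAT5 and cytokine target genes rose in 5 of 16 cases, with 7 higher and 1 lower adjusted over the list alone (median 0.58, adjusted p = 0.0069, and adjusted p = 0.248 with an estimated correlation). Socs2, a feedback inhibitor of cytokine signalling, went from 3.47 ± 1.93 to 17.6 ± 0.636 FPKM, and Id1, Bcl6 and Socs1 rose by 1.54, 1.31 and 0.92 on the log2 scale. Immediate early genes rose in 3 of 11 cases, Klf6 by 1.05, Klf2 by 1.38 and Ier2 by 0.84 (median 0.68, adjusted p = 0.0208, and adjusted p = 0.616 with an estimated correlation; 3 also adjusted over the list alone). Without Flt3-ITD replicate 1 the adjusted p of this list was 0.0547. Interferon response genes went both ways, with 4 of 26 lower and 2 higher, the same numbers adjusted over the list alone (median -0.59, adjusted p = 0.0284, and adjusted p = 0.616 with an estimated correlation). Oas1a, Isg15, Rtp4 and Xaf1 fell by 1.91, 1.58, 2.33 and 1.10 on the log2 scale, of which Oas1a is uncertain because of its close paralogs. The list's adjusted p was 0.0643 without Flt3-ITD replicate 2 and 0.166 in the table the authors normalized.

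In all, 1955 genes differed between Flt3-ITD and control by limma, 924 higher and 1031 lower. Among the largest rises outside the lists were Cp, ceruloplasmin, with a log2 fold change of 2.56 ± 0.424 (SE), Ifitm1 (2.54 ± 0.29), Stap2 (2.39 ± 0.229), Enah (2.29 ± 0.236), Klrb1f (2.20 ± 0.34) and 4632427E13Rik (2.05 ± 0.54). D330023K18Rik was listed at 0 in both controls and at 7.97 and 3.29 FPKM in Flt3-ITD. Short RNA genes were irregular: Snora44 was listed at 0 in every library except Flt3-ITD, with 223 and 127 FPKM, and Rnu12 was at 41.4 and 14.6 in Flt3-ITD. Mir5133 was at 79427 and 33515 FPKM in controls, 0 and 21640 in Smc3 del/+ and 0 in the other 4 libraries. Snord22 was at 253 and 68.7, 0 and 72.6, and 0 in the others. Xist was lower in Flt3-ITD with a log2 fold change of -9.02. In the table the authors normalized, the median of all genes shifted by -0.58 and 4783 genes were called, 107 higher and 4676 lower. Of the 1955 genes, 41 had the opposite sign there. Leaving out a library gave from 243 genes, without control replicate 1, to 4235, without combined replicate 2, with 311, 996, 994, 443, 811 and 4232 genes without control replicate 2, Smc3 del/+ replicates 1 and 2, Flt3-ITD replicates 1 and 2 and combined replicate 1.

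**Figure D3:**
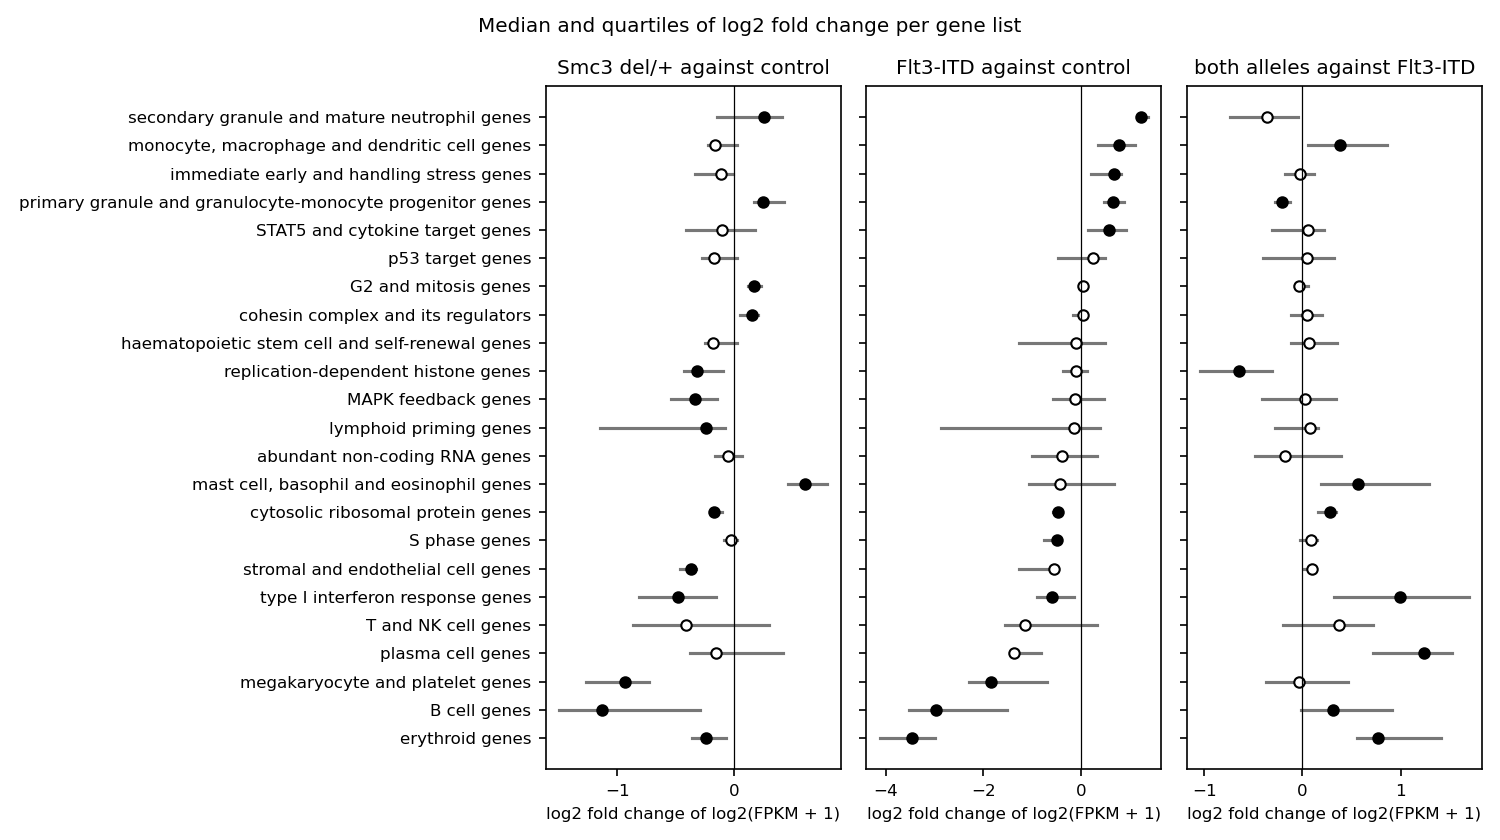
Median log2 fold change of log2(FPKM + 1) (x axes) of each of 23 gene lists (y axis) in the 3 main comparisons; points are medians over tested members, lines span the quartiles, and filled points passed camera at an adjusted p of 0.05 with the preset correlation. Erythroid genes have a median of -3.46 in Flt3-ITD against control and of 0.77 in the combined group against Flt3-ITD, and megakaryocyte and platelet genes have medians of -0.94 and -1.84 in the comparisons with control.

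The MHC class II genes H2-Aa and H2-Eb1 and their chaperone gene Cd74 were higher in the combined group than in Flt3-ITD, in the comparison that asks what the Smc3 deletion adds to the Flt3 mutation. H2-Aa, an MHC class II chain, rose from 17.3 ± 9.30 to 160 ± 42.0 FPKM (log2 fold change 3.22 ± 0.366 SE, limma adjusted p = 0.0331), H2-Eb1 from 10.3 ± 7.67 to 93.3 ± 14.3 (3.25 ± 0.423) and Cd74, the invariant chain, from 91.7 ± 50.9 to 789 ± 349 (3.13 ± 0.408). These calls depended on the processing and on the spread shared with the other groups. Only 1 gene was called higher when the fit held the 2 compared groups alone. With a pseudocount of 0.1 the limma adjusted p of H2-Aa, H2-Eb1 and Cd74 was 0.0505, 0.0554 and 0.0505. Without a filter on low values it was 0.0796, 0.104 and 0.104, at unchanged log2 fold changes. H2-Ab1 was at 222 ± 74.5 against 34.5 ± 23.9 and did not pass (adjusted p = 0.0709). Of 22 tested dendritic cell markers, a list made after the results were seen that holds these 4 genes, 17 were higher in both combined libraries than in both Flt3-ITD libraries. In the monocyte, macrophage and dendritic cell list, 2 of 22 rose, 4 adjusted over the list alone (median 0.38, camera adjusted p = 0.000687, and adjusted p = 0.554 with an estimated correlation). In the B cell list the only member called was Cd74, and 2 were higher adjusted over the list alone (median 0.32, adjusted p = 0.0093, and adjusted p = 0.785 with an estimated correlation). Without combined replicate 1 the adjusted p of these lists was 0.371 and 0.157.

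Type I interferon response genes were also higher in the combined group, 24 of 26 in mean, of which 2 passed among all genes and 13 adjusted over the list alone (median 0.99, camera adjusted p = 2.61e-12, and adjusted p = 0.263 with an estimated correlation). Oas1a, uncertain because of its paralogs, was at 8.46 ± 2.04 FPKM against 0.662 ± 0.365, Mx1 at 4.48 ± 0.777 against 0.483 ± 0.0893, and Isg15, which did not pass, at 3.17 ± 0.726 against 0.261 ± 0.22. Controls, which share the female Xist pattern, had Oas1a at 5.17 ± 0.209, Mx1 at 0.634 and 0.566, and Isg15 at 2.74 ± 0.0075. Erythroid genes were higher in 22 of 26 cases, with none called among all genes and 8 adjusted over the list alone (median 0.77, adjusted p = 1.23e-09, and adjusted p = 0.485 with an estimated correlation). Klf1, an erythroid transcription factor, was at 7.89 ± 3.29 FPKM against 1.79 ± 1.26 in Flt3-ITD and 46.8 ± 6.61 in controls, and Rhag was at 9.16 and 23.4 in the combined replicates against 4.28 and 1.42. The mean of the erythroid list on the log2(FPKM + 1) scale was 2.52 and 3.43 in combined replicates 1 and 2 against 2.38 and 1.74 in Flt3-ITD, so that most of the difference lay in combined replicate 2. Of 13 mast cell, basophil and eosinophil genes, 1 rose and 5 were higher adjusted over the list alone (median 0.56, adjusted p = 0.000186, and adjusted p = 0.263 with an estimated correlation). It was Prg2, at 186 ± 59.8 against 43.7 ± 6.13 FPKM. Epx was at 19.8 ± 18.6 against 1.94 ± 0.568 and did not pass. Without combined replicate 1 the adjusted p of this list was 0.0874. Megakaryocyte and platelet genes had a median of -0.04 with no call (camera adjusted p = 0.801).

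Of 10854 genes, 31 differed between the combined group and Flt3-ITD, 26 higher and 5 lower. The libraries of these groups did not overlap in 3679 genes (33.9%), against 33.3% by chance, in genes that are not independent. The calls also draw on the spread of the other groups. When only the 2 compared groups were in the fit, 2 of the 31 genes kept their call. Further large rises were in Ifi205, an interferon-inducible gene, from 27.8 ± 3.32 to 164 ± 8.02 FPKM, Klrd1 (2.43 ± 0.307 on the log2 scale, SE) and Stfa2 (2.83 ± 0.3), whose family of close paralogs makes its value uncertain. 2510003D18Rik was listed at 0 in both Flt3-ITD libraries and was at 3.81 and 6.05 in the combined group. The 5 lower genes were Nt5e, the CD73 ectoenzyme, at 0.125 ± 0.176 against 4.05 ± 0.121, Tex15 at 4.62 ± 1.20 against 17.3 ± 2.49, Lhfpl2 at 2.46 ± 0.859 against 9.82 ± 0.78, and the short RNA genes Snora44 and Rnu12, listed at 0 in the combined group. Xist was higher with a log2 fold change of 8.80. The count rests on the libraries used: it was 3, 3, 4, 4, 6 and 7 without control replicates 1 and 2, Smc3 del/+ replicates 1 and 2 and Flt3-ITD replicates 1 and 2, but 3248 without combined replicate 1 and 111 without combined replicate 2. In the first 6 of these, 3, 3, 4, 4, 5 and 4 of the 31 genes kept their call, and in the last 2 all 31 did. The median of all genes shifted by -0.107 in the table the authors normalized, where 25 were higher and 6 lower. The combined pair differed with an SD across genes of 0.701 on the log2 scale, against 0.393, 0.350 and 0.409 in the control, Smc3 del/+ and Flt3-ITD pairs.

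Against control, the combined group had 1279 changed genes, 587 higher and 692 lower, in groups of the same Xist pattern. In the table the authors normalized these were 121 higher and 5795 lower, with a median shift of all genes of -0.67. Erythroid genes fell in 23 of 26 cases, 24 adjusted over the list alone (median -2.52, camera adjusted p = 9.89e-17, and adjusted p = 0.301 with an estimated correlation). Megakaryocyte and platelet genes fell in 12 of 18, 13 adjusted over the list alone (median -1.49, adjusted p = 5.68e-10, and adjusted p = 0.0474 with an estimated correlation). Monocyte, macrophage and dendritic cell genes rose in 11 of 22 and fell in 2, 15 and 3 adjusted over the list alone (median 1.09, adjusted p = 6.05e-06, and adjusted p = 0.316 with an estimated correlation). The largest rises were H2-Aa (4.09 ± 0.366 on the log2 scale, SE), H2-Eb1 (4.05 ± 0.423), Cd74 (3.75 ± 0.408), Bcl2a1a (3.62 ± 0.674) and Ear1, at 93.0 and 39.5 FPKM against 7.48 and 2.03, the last 2 from families of close paralogs and so uncertain. Igll1 and Ppbp fell by 5.39 and 4.31. Mir5133 and Snord22 were listed at 0 in the combined group, and Snora81 too, against 46.6 and 40.3 in controls. Kit had a log2 fold change of -0.56 ± 0.136 (adjusted p = 0.0391), and did not pass without control replicates 1 and 2 (0.255 and 0.164) or Smc3 del/+ replicates 1 and 2 (0.0961 and 0.0962). With only these 2 groups in the fit 41 genes were called. Leaving out 1 library gave 86 and 83 without control replicates 1 and 2, 514 and 517 without Smc3 del/+ replicates 1 and 2, and 3113 and 3427 without combined replicates 1 and 2.

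The average over both Smc3 backgrounds is balanced for the sex of the mice, but not for Mx1-cre, which the controls lack. In it, Flt3-ITD changed 2581 genes, 1187 higher and 1394 lower. In the normalized table the numbers were 221 and 4791, with a median shift of -0.44. Erythroid genes fell in 24 of 26 cases, S phase genes in 15 of 22 and B cell genes in 11 of 16 with 1 higher, while 16 of 22 monocyte, macrophage and dendritic cell genes rose and 4 fell (camera adjusted p = 4.72e-17, 1.14e-07, 2.15e-06 and 0.000134). Adjusted over the list alone these were 24 lower and 1 higher, 17 lower, 14 lower and 1 higher, and 17 higher and 4 lower. Each of the 4 lists had an adjusted p of 0.445 with an estimated correlation. Socs2 (3.06 ± 0.384 on the log2 scale, SE), Ifitm1 (2.76 ± 0.208), Cp (2.65 ± 0.286), H2-Aa (2.50 ± 0.608) and S100a4 (2.35 ± 0.378) had the largest rises among genes whose libraries did not overlap. H2-Aa was at 190 and 131 FPKM in the combined group, 23.9 and 10.7 in Flt3-ITD and 8.18 and 8.52 in controls. Most of its averaged rise therefore lay in the combined group. H2-Aa did not pass without Smc3 del/+ replicate 1, Smc3 del/+ replicate 2 or Flt3-ITD replicate 1 (adjusted p = 0.0528, 0.0653 and 0.0544). Igll1 (-4.39 ± 0.467), Ermap (-3.67 ± 0.516), Aqp1 (-3.57 ± 0.48) and the globin gene Hba-a2 (-3.47 ± 0.569), whose reads a near-identical copy can share, had the largest falls. Sh2d4a was at 13.4, 14.3, 12.1 and 11.2 FPKM without Flt3-ITD, at 0 in both Flt3-ITD libraries and at 0.698 and 0 in the combined group. Leaving out 1 library gave 1208 and 1260 genes without control replicates 1 and 2, 1446 without Smc3 del/+ replicate 2, 1529 and 1525 without Flt3-ITD replicates 1 and 2, and 4703 without combined replicate 2.

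Averaged over both Flt3 backgrounds, the Smc3 deletion as labelled changed 0 genes by limma, with 525 at an unadjusted p under 0.05. This average is again balanced for sex but not for Mx1-cre. Without Flt3-ITD replicate 2, 1 gene was called. In the table the authors normalized, 3 were lower, with a median shift of all genes of -0.238. Mast cell, basophil and eosinophil genes were higher as a group, 13 of 13 in mean and 7 adjusted over the list alone (median log2 fold change 0.58, camera adjusted p = 2.59e-10, and adjusted p = 0.0215 with an estimated correlation). Prg2 was at 54.6, 75.5, 228 and 143 FPKM in the 4 labelled libraries and at 25.3, 27.3, 48.0 and 39.3 in the others (log2 fold change 1.64 ± 0.212 SE, adjusted p = 0.132). Prss34, Ear1 (uncertain, as above) and Mcpt8 had log2 fold changes of 0.79, 2.11 and 0.37. Megakaryocyte and platelet genes had a median of -0.62, with 5 of 18 lower adjusted over the list alone (adjusted p = 1.26e-08, and adjusted p = 0.417 with an estimated correlation). Gp1bb, Clec1b and Itga2b had log2 fold changes of -1.04, -0.81 and -0.53, and Gp9 was at 2.20, 3.29, 0.514 and 0 FPKM in the labelled libraries against 5.26, 5.30, 2.35 and 1.52. Other genes that did not pass were St8sia6 (1.10 ± 0.189) and Lysmd2 (1.12 ± 0.223), and, on the lower side, Ceacam10 (-1.84 ± 0.205), Tex15 (-1.41 ± 0.177) and Nt5e (-1.63 ± 0.263).

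The effects of the Smc3 deletion as labelled were compared between the 2 Flt3 backgrounds. Across 10854 genes, which are not independent, the log2 fold changes of Smc3 del/+ against control and of the combined group against Flt3-ITD had a Pearson r of -0.13, in comparisons that are of opposite sex. Those of Smc3 del/+ and of Flt3-ITD, each against the same controls, had r = 0.53 and a covariance of 0.137. Simulated groups without any effect gave r = 0.50 and a covariance of 0.0429 with shared controls (100 simulations), a difference in covariance of 0.0941. With a separate control for each comparison, a test chosen after the results were seen, r was 0.379 and 0.261 and the covariance 0.113 and 0.0839 for the 2 ways of assigning the controls. Both groups also share the male Xist pattern and Mx1-cre, which the controls lack.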

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

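The tests of the sex of the mice, of dendritic cell markers, of the shift toward control and principal component 2, of the platelet gene members and of the replicate spread without short RNA genes were chosen after the results were seen; the replicate spread in its first form and the splits of the libraries were set before.

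Some effects of the Smc3 deletion differed with the Flt3 background in a test of the interaction (limma, 4 of 10854 genes; 1009 at an unadjusted p under 0.05). Xist had an interaction of 17.4 on the log2 scale, which is the sex of the mice. Ifi205 had 2.83: it was at 18.8 and 20.5 FPKM in controls, 13.1 and 18.7 in Smc3 del/+, 30.1 and 25.4 in Flt3-ITD, and 169 and 158 in the combined group. Rnu12 (-9.32) and Snora44 (-7.40) were listed at 0 in whole groups, so these fitted values depend on the pseudocount. Lists also differed by camera with the preset correlation: B cell genes (median 1.46), type I interferon response genes (1.39), megakaryocyte and platelet genes (1.19), erythroid genes (1.12), monocyte, macrophage and dendritic cell genes (0.448), ribosomal protein genes (0.395), G2 and mitosis genes (-0.195), and primary granule and granulocyte-monocyte progenitor genes (-0.484). None of the 8 passed with an estimated correlation; with the preset one, the monocyte, macrophage and dendritic cell list did not pass without combined replicate 1 (adjusted p = 0.235), and the G2 and mitosis list without control replicate 2, Smc3 del/+ replicate 2, Flt3-ITD replicate 1 or combined replicate 1 (0.0924, 0.0773, 0.641 and 0.9). Genes that did not pass included Oas1a (3.56) and Hist1h2bc (-1.66), both uncertain because of close paralogs, with limma adjusted p of 0.0717 each. In place of 4 genes, 7 were called without control replicate 1, 7 without Smc3 del/+ replicate 2, 2036 without combined replicate 1 and 98 without combined replicate 2. In the table the authors normalized, 17 were higher and 2 lower, with a median shift of all genes of 0.266. The interaction follows sex in full, so no gene or list here can be credited to the alleles alone.

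Over the 24 called genes higher in the combined group than in Flt3-ITD, other than Xist and Eif2s3x, the median difference was 2.24 on the log2 scale. That of control over Smc3 del/+, the other female and male pair, was 0.14 with an upper quartile of 0.323, under the bound of 1.12. The 24 genes were selected for a large difference in the first pair, which can enlarge its median and the bound taken from it. These values therefore do not decide whether sex was their only cause, even if sex acts alike in both Flt3 backgrounds. Effects of sex and of the deletion that cancel between control and Smc3 del/+ and add up here also stay open. Of 22 tested dendritic cell markers, 6 of which the monocyte, B cell or lymphoid lists also hold, 17 (77.3%) were higher in both combined libraries than in both Flt3-ITD libraries; the list was made after the rises were seen and 4 of the 22 are among the called genes, so this share decides nothing. By type these were 9 of 11 conventional dendritic cell, 6 of 7 antigen presentation and 2 of 4 plasmacytoid markers; Cd74 reached 1036 and 541.7 FPKM and Cst3, chosen after its values were seen, 256.1 and 155.9. A larger share of dendritic cells in the bead-selected fraction and a change within progenitors that carry both alleles both stay open. For the interferon list, the sex of the mice cannot be told apart from the alleles: control over Smc3 del/+ had a median of 0.481 with quartiles of 0.153 and 0.811, which lie on both sides of the bound of 0.494 (the combined group over Flt3-ITD had 0.988).

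The combined pair differed more than the other pairs. The test set beforehand, the SD of the replicate difference among genes at 300 FPKM or more, gave a ratio of 0.333 to the largest other pair, but 5 short RNA genes set that other SD (1.73 in controls with them and 0.153 without), so it decided nothing. Repeated without short RNA genes, the ratio was 2.01 (0.575 against 0.286), which argues against few distinct molecules in replicate 2 as the whole cause, even though that library had 171 genes between 0.01 and 0.1 FPKM against 611 to 1180 in the others. Replicate 2 lay nearer to control than replicate 1 over genes called between Flt3-ITD and control, by medians of 0.254 for the genes that rose and 0.216 for those that fell. On principal component 2 of the libraries (20.6% of the variance), however, it had a score of -53.35 against 1.701 to 14.44 in the other 7, which argues against a position between control and Flt3-ITD as the whole cause; what sets that library apart stays open.

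Megakaryocyte and platelet genes were lower in libraries labelled Smc3 del/+, which are of male pattern, and in the other female and male pair, the combined group over Flt3-ITD, the list had a median of -0.0391 where control over Smc3 del/+ had 0.936. That value cannot tell sex from the allele, because 10 of the 18 members were under 2 FPKM in Flt3-ITD, too low for a change to show; this reading was adopted after an earlier one, which took the value as evidence against sex, had been written. All members (100%, 18 of 18) were lower in both Smc3 del/+ libraries than in both controls, which restates the pattern and decides nothing about its cause. Fewer cells of that lineage and lower expression within them both stay open.

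With the 8 libraries split into 4 and 4 in 35 ways, the real split by Flt3-ITD gave 2581 genes and the highest other split 2. Thus 1 of 35 splits gave as many, the smallest share these splits allow. This argues against a chance split as the source of that count, without excluding it. For the Smc3 deletion, the real split gave 0 genes, a number that all 35 splits must reach, so this count says nothing about chance; the highest other split, with 2615 genes, was the split by Flt3-ITD, the main structure of these samples.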

How the results depend on the processing

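The alternatives without short RNA genes, without both combined libraries, with sex as an additional factor and with separate controls were chosen after seeing the data. Counts of called genes moved as follows, and the causes were not tested. Smc3 del/+ against control had 1 gene, and 12 in the normalized table, 3 with a pseudocount of 0.1, without a filter or without the variance trend, 5 with quantile scaling, 22 with only the compared groups, 12 without both combined libraries, and 1 to 12 with 1 library left out. Flt3-ITD against control had 1955, and 4783 in the normalized table, 3603 with only the compared groups, 4231 without both combined libraries, and 243 to 4235 with 1 left out. The combined group against Flt3-ITD had 31, and 5 with a pseudocount of 0.1, 9 without a filter, 17 with a mean of at least 5 FPKM, 2 with only the compared groups, and 3 to 3248 with 1 left out. The combined group against control had 1279, and 5916 in the normalized table, 41 with only the compared groups, and 83 to 3427 with 1 left out. The interaction had 4, and 19 in the normalized table, 2 without a filter, 7 without the variance trend, 2 without short RNA genes (2 of the 4 are such genes), and 4 to 2036 with 1 left out. The averaged Smc3 effect had 0, and 3 in the normalized table, 1 with sex as an additional factor, and 0 to 1 with 1 left out; averaged Flt3-ITD had 2581, 5012 in the normalized table, and 1208 to 4703. Of the 1955 genes, 1138 kept their call in the normalized table and 41 changed sign there; 237 kept it without control replicate 1.

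The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at -0.113 to 0.0229 between groups. With the replicate number as a block, the combined group against Flt3-ITD had 3 genes and the averaged Smc3 effect 1, and the other counts stayed within 1.5 times.

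Lists called fell with an estimated correlation from 14 to 1 for Smc3 del/+ against control, 11 to 0 for Flt3-ITD against control, 9 to 0 for the combined group against Flt3-ITD, 12 to 1 for the combined group against control, 8 to 0 for the interaction, 7 to 1 for averaged Smc3 and 10 to 0 for averaged Flt3-ITD. In the normalized table the first was 9. With 1 library left out they were 9 to 14, 5 to 10 and 3 to 9 for Smc3 del/+ against control, the combined group against Flt3-ITD and averaged Smc3.

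Directions that turned: the Smc3 level in Smc3 del/+ against control (0.21) was -0.13 in the normalized table; in the combined group against control (0.04) it was -0.65 there, -0.0788 with quantile scaling and -0.16 to 0.23 with 1 left out; its interaction (0.14) was -0.0575 to 0.339; in the combined group against Flt3-ITD it was 0.16 to 0.55, past the threshold without combined replicate 1. Kit in Flt3-ITD against control (-0.12) was -0.25 to 0.0043, and averaged Flt3-ITD on Flt3 (0.37) was -0.0780 in the normalized table. Camera turned for histone genes in Smc3 del/+ against control (-0.344 relative to all genes in the normalized table, -0.638 to 0.0254 with 1 left out), and for averaged Smc3 in G2 and mitosis genes (0.0676 in the normalized table) and interferon genes (0.015 to 0.41). The correlations of effects were -0.172 to -0.0618 and 0.436 to 0.595 with 1 left out, and the second was 0.379 and 0.261 with separate controls. Of the named genes past the threshold, 22 of 60 for Flt3-ITD against control, 2 of 17 for the combined group against Flt3-ITD and 9 of 10 for averaged Flt3-ITD stayed past it under every alternative in which they were tested. Where a group keeps 1 library, that library is assumed to vary like the other groups. Depth in reads is unknown, which limits what can be said of genes listed at 0.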

Other observations

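Gene groups not described so far had these values, in tests fixed beforehand. Replication-dependent histone genes had a median log2 fold change of -0.65 in the combined group against Flt3-ITD (camera adjusted p = 0.000302, and adjusted p = 0.485 with an estimated correlation) and of -0.45 for the averaged Smc3 deletion (adjusted p = 4.46e-06, and adjusted p = 0.417 with an estimated correlation), with no member of 19 called in either. Haematopoietic stem cell and self-renewal genes went both ways with Flt3-ITD averaged over both Smc3 backgrounds, 4 of 17 higher and 5 lower, 5 and 6 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.95, in the lower direction, so that median and test differ in sign). MAPK feedback genes had 3 of 8 higher and 1 lower there, 3 and 3 adjusted over the list alone (median 0.18, adjusted p = 0.788). The p53 target genes had 1 of 11 higher and 1 lower, 1 and 2 adjusted over the list alone (median 0.03, adjusted p = 0.788). Plasma cell genes had a median of 1.24 in the combined group against Flt3-ITD with no member of 4 called and 3 higher adjusted over the list alone (adjusted p = 0.0491, and adjusted p = 0.485 with an estimated correlation); without Flt3-ITD replicate 1, combined replicate 1 or combined replicate 2 the adjusted p was 0.151, 0.165 and 0.0898. T and NK cell genes (median 0.38), stromal and endothelial cell genes (0.10) and abundant non-coding RNA genes (-0.18) did not pass in that comparison, where 1 T and NK cell gene, Klrd1, was higher, with adjusted p of 0.493, 0.647 and 0.547.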
